A study of Mus musculus with 36 samples.

How the data were processed

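RNA from 36 mouse pancreatic tumours was measured on the nCounter PanCancer Immune Profiling Panel for mouse, an assay that counts barcoded probes hybridised to RNA without amplification. The panel held 750 endogenous genes, 20 housekeeping genes, 6 positive controls and 8 negative controls. Per the labels, KPfC BMF-A3 cells, a mouse pancreatic tumour line, were implanted into the pancreas of C57BL/6 mice. Treatment began on day 10 and tumours were taken on day 35, per the labels' protocols. TP-0903, an inhibitor of the receptor kinase Axl, was given by mouth at 25 mg/kg daily, per the same protocols. Gemcitabine, a nucleoside analogue, was injected at 25 mg/kg 3 times a week, and the PD1-blocking antibody at 5 mg/kg 2 times a week, per the same protocols.

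The authors deposited a value table of whole-number counts for 770 genes in every tumour. Per the series' design text, tumour RNA was prepared at a core facility and the values were normalized to positive controls and to the geometric mean of the housekeeping genes. The deposited table nevertheless held raw counts, because 27720 of 27720 values were identical to those in the authors' raw lane report. The deposited lane report mixed counts with other values, namely lane attributes such as binding density, and supplied the control probes and the cartridge of each lane, per the file headers. No normalized values were available, so the alternatives set in advance on the authors' normalized values, with a pseudocount of 1 and of 20, were not run. In the lane report, 7 lane identifiers carried a suffix whose meaning no header or label gave. Gene symbols were those of the lane report, and 746 of 770 probe accessions matched the RefSeq gene table of assembly GRCm38.p6, 9 of them under another symbol. No coordinates were used.

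Groups were taken from the labels, which formed a factorial design of 3 agents with 8 arms. Total counts per tumour ranged from 115973 to 552876, and depth limited the genes near background rather than abundant genes. A gene was tested if its count lay above the lane's negative-control mean plus 2 SD in at least 4 lanes. This filter left 683 genes tested and 67 untested. Library sizes were scaled to the geometric mean of the 20 housekeeping genes in each lane. Scaled counts in the text are raw counts divided by these factors, and errors of arm means are SD. An arm was called at background for a gene where none of its libraries exceeded its lane's threshold. For some of these genes, not all, the fold was also given as a bound ("at least"), computed from geometric means over libraries. Each library of the arm at background was set to the higher of its own value and its lane's threshold.

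The test in each comparison was edgeR's quasi-likelihood test with robust dispersion estimates (edgeR 4.0.16, limma 3.58.1, R 4.3.3), two-sided, with all 36 libraries and 8 arms in a single fit. Log2 folds are given with their standard error. Benjamini-Hochberg adjustment ran within each comparison, and genes with an adjusted p under 0.05 were called. The 16 comparisons were each of the 7 treated arms against vehicle, TP-0903 added to each of the 3 other regimens, the average effect of each agent over the 4 backgrounds of the other agents, and the 3 interactions between pairs of agents. An average effect was the mean of 4 contrasts, and an interaction was the difference between an agent's effect with and without the other agent, averaged over the third agent. The common biological coefficient of variation was 0.477.

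Lists of 24 gene groups, with 416 members of which 388 were on the panel, were fixed and tested with fry, a rotation test in limma of whether the members of a list move on balance 1 way. The lists were T cell core, cytotoxic lymphocyte and NK cell, regulatory and helper T cell factors, immune checkpoints, B cell and plasma cell, MHC class I presentation, MHC class II presentation, type I interferon response, interferon gamma induced, macrophage and monocyte, suppressive myeloid factors, neutrophil, dendritic cell, mast cell and eosinophil, TAM receptor pathway, endothelial and angiogenesis, stroma with matrix and mesenchymal genes, epithelial and tumour cell, complement, NF-kB and inflammatory cytokines, cell cycle and p53, and markers of normal pancreas, of lymph node or spleen, and of liver. A list needed at least 3 tested members, so 23 lists were tested in each comparison and the normal pancreas list was not, having 2 tested members. List p-values were adjusted over the lists of a comparison. Camera with a preset correlation of 0.01 and with an estimated correlation served as alternatives. The lung marker list of 5 genes was written after the values had been seen and only describes libraries.

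The genes named were chosen by a rule. Among called genes it took the 10 largest and the 10 smallest log2 folds, and where fewer than 5 genes were called it took the 5 smallest p-values. The rule also took Axl, Mertk, Pdcd1, Cd274, Cd8a, Cd4, Foxp3, Gzmb, Ifng, Cd68, Arg1, Mrc1, S100a8, H2-K1, H2-Ab1, Cxcl9, Cdh1, Vim and Col1a1, and the 4 members with the smallest p of each list described. Not every gene that the rule takes is printed. Groups, tests, lists, the naming rule and the first set of alternatives were fixed before the data were examined.

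The alternatives fixed in advance were TMM scaling, scaling to positive controls only, DESeq2 1.42.0 with its own size factors, limma on log2 scaled counts plus 1, limma after subtracting the negative-control mean with a floor of 1, no filter, a filter requiring 18 lanes and leaving 565 genes, a fit to only the groups compared, the cartridge as a block, the first digit of the number in the title (7 in 24 titles and 8 in 12) as a block, and leaving out each library in turn. Alternatives added after the data had been seen left out 2 libraries with high markers of liver or lung, or 3 with the next highest liver markers, and combined the first of these with TMM, limma, DESeq2 or the cartridge block. Comparisons within the cartridge that held lanes of both arms and list tests with the cartridge block were also added then. Correlations between comparisons that share the vehicle libraries were set beside 50 simulations of unchanged groups and beside splits of the vehicle libraries into separate controls.

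The procedure was tested on simulated data drawn from the real libraries' means and sizes, with 50 genes changed at each fold size. In the simulated comparison of TP-0903 with vehicle over 683 genes, edgeR recovered 54% of the genes changed 2-fold, 80% of those changed 4-fold and 100% of those changed 8-fold, with 3 false calls. In the simulated triple-therapy comparison it recovered 44%, 90% and 98% at the same sizes. A neutrophil list raised 2-fold was called in 10 of 10 simulated sets, and an unchanged list in 0 of 10. The simulation drew each gene independently and held no library that stood apart. Other splits of the real TP-0903 and vehicle tumours called up to 225 genes. The simulated rates therefore do not give the error rate or power for these tumours.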

Results

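Transcripts of immune, stromal and tumour genes were counted in 36 orthotopic pancreatic tumours from mice given every combination of an Axl inhibitor (TP-0903), gemcitabine and a PD1-blocking antibody. Vehicle tumours numbered 6, the arms TP-0903+Gemcitabine and TP-0903+Gemcitabine+anti-PD1 held 5 each, and the other 5 arms, TP-0903, Gemcitabine, Anti-PD1, TP-0903+anti-PD1 and Gemcitabine+anti-PD1, held 4 each. Total counts per tumour had a median of 357262 and ran from 115973 to 552876, the lowest in TP-0903+anti-PD1 replicate 4. The geometric mean of the housekeeping genes ran from 146 to 540. Between 461 and 674 genes exceeded the lane's background threshold, which lay between 8.21 and 26.3 counts. No pair of libraries within an arm was a duplicate, since the closest pair differed by 5.14 times the counting variance per gene. The lanes came from 3 cartridges of 12 lanes. Cartridge 1 held all vehicle and TP-0903 lanes and 2 Gemcitabine lanes, so Anti-PD1, TP-0903+Gemcitabine, TP-0903+anti-PD1, Gemcitabine+anti-PD1 and TP-0903+Gemcitabine+anti-PD1 shared no cartridge with vehicle. All adjusted p-values for genes come from edgeR unless another tool is named.

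Axl, the receptor kinase that TP-0903 inhibits, was expressed at 634 ± 156 scaled counts in vehicle tumours (SD, n = 6) and at 562 ± 266 after TP-0903 (n = 4). Its log2 fold was -0.17 ± 0.28 (SE), an edgeR adjusted p of 0.809. Averaged over the 4 backgrounds the log2 fold of Axl with TP-0903 was 0.01 ± 0.14 (adjusted p = 0.996). Pdcd1, which encodes PD1, was near background at 13.2 ± 5.89 scaled counts in vehicle tumours and 10.4 ± 2.13 after Anti-PD1 (n = 4), and its average log2 fold with the antibody was -0.26 ± 0.19 (adjusted p = 0.866). Both treatments act on protein, so these transcripts do not check the labels. Mertk, a receptor related to Axl, had an average log2 fold of 0.04 ± 0.19 with TP-0903 (adjusted p = 0.973).

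**Figure D1:**
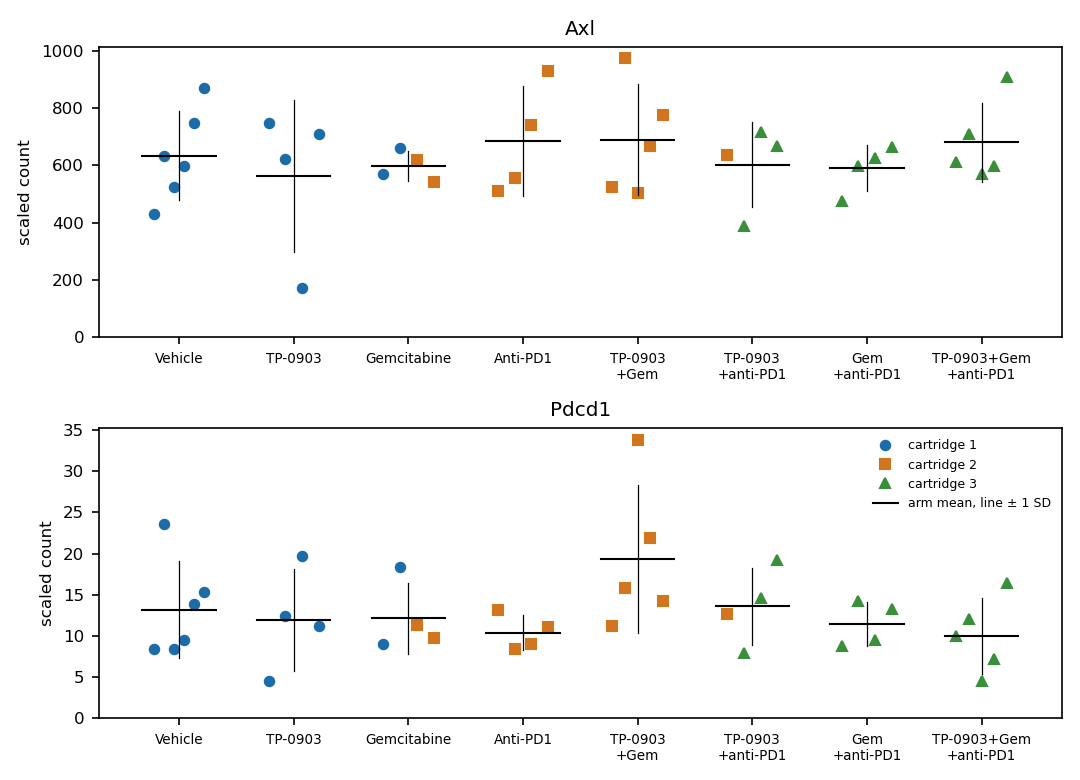
Housekeeping-scaled counts of Axl and Pdcd1 in each of the 36 tumours by arm, with points coloured by cartridge and bars giving the arm mean ± 1 SD. Axl arm means lay between 562 and 689 and those of Pdcd1 between 10.0 and 19.4, each within the spread between tumours.

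Of the 19 genes fixed as always named, Cd8a, Foxp3 and Gzmb, which mark CD8 T cells, regulatory T cells and killing lymphocytes, did not pass the filter and were not detectable as different at this depth. The remaining 16 genes gave 256 tests over the 16 comparisons, of which 1 was called (Arg1, TP-0903 against vehicle) and 11 had an unadjusted p under 0.05. The call of Arg1, which hepatocytes express as well, went with liver genes in TP-0903 replicate 3, and without that library and Vehicle replicate 3 its log2 fold was 0.38 ± 0.52. With TP-0903, the average log2 fold was 0.93 ± 0.39 for Arg1, an arginine-degrading enzyme (adjusted p = 0.339), 0.50 ± 0.23 for the mannose receptor Mrc1 (0.393) and 1.20 ± 0.44 for the neutrophil alarmin S100a8 (0.317). Cxcl9, a chemokine that draws T cells, averaged 0.42 ± 0.44 with TP-0903 (adjusted p = 0.799), 0.16 ± 0.44 with the antibody (0.942) and -1.02 ± 0.44 with gemcitabine (0.274). The PD1 ligand gene Cd274 averaged -0.02 ± 0.16, 0.18 ± 0.16 and 0.11 ± 0.16 with TP-0903, the antibody and gemcitabine. The helper T cell gene Cd4 averaged -0.27 ± 0.21, -0.12 ± 0.21 and 0.04 ± 0.21 in that order, and Ifng, near background, 0.03 ± 0.21, -0.13 ± 0.21 and 0.12 ± 0.21. For the macrophage gene Cd68 these values were 0.14 ± 0.14, 0.11 ± 0.14 and 0.14 ± 0.14. The presentation genes H2-K1 and H2-Ab1 averaged 0.22 ± 0.31 and -0.57 ± 0.36 with TP-0903, -0.47 ± 0.31 and -0.33 ± 0.36 with the antibody, and -0.59 ± 0.31 and 0.06 ± 0.36 with gemcitabine. Among tumour and stromal genes, average folds with TP-0903 were -0.34 ± 0.17 for Cdh1, 0.05 ± 0.22 for Vim and 0.17 ± 0.35 for Col1a1. None of these averages passed the threshold.

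TP-0903 alone was set against vehicle to ask what Axl inhibition does to the tumour's immune transcripts. Genes of hepatocytes rose: H2-Q10, a secreted class I molecule, by a log2 fold of 8.15 ± 1.32 (n = 4 and 6), the iron hormone gene Hamp by 7.82 ± 1.69, the acute-phase gene Saa1 by 7.66 ± 1.25, the complement gene C8a by 7.36 ± 1.27 (at least 1.68-fold, the vehicle arm being at background), the lectin Mbl2 by 7.24 ± 1.19, the tryptophan enzyme Tdo2 by 7.16 ± 1.41, the plasma protein Ambp by 6.91 ± 1.39, and C9, C8g and the clotting factor F12 by 6.63 ± 1.03, 6.40 ± 0.98 and 6.26 ± 1.17 (C8g at least 4.22-fold and F12 at least 2.79-fold). Arg1 rose by 3.12 ± 0.76, from 548 ± 405 to 4755 ± 7811 scaled counts (adjusted p = 0.00823, 4 of 4 above the vehicle mean). The neutrophil chemokine Cxcl1 rose by 3.91 ± 0.78 and the cytokine Osm by 0.96 ± 0.29. Genes of lung epithelium fell, Cxcl15 by a log2 fold of -6.88 ± 1.62 and Lamp3 by -4.65 ± 1.21, as did the complement gene C7 at -3.66 ± 1.09 (at least 1.36-fold lower). In all, 33 genes were called, 30 higher and 3 lower, and 99 had an unadjusted p under 0.05. A single tumour carried most of this: without TP-0903 replicate 3 the count was 0, and H2-Q10 stood at 40065 scaled counts in that tumour against 29.8 to 199 in the other 3. The epithelial gene Epcam stood at 43.2 there against 2142 to 2293 and Cdh1 at 485 against 1761 to 2526, so epithelial genes were lower in that library by unequal amounts. In an added fit without that library and Vehicle replicate 3 the count was again 0 (43 unadjusted; limma 0, DESeq2 0), with log2 folds of 1.45 ± 0.76 for H2-Q10, 2.40 ± 1.20 for Hamp, 3.09 ± 0.91 for Saa1 (adjusted p = 0.505), 0.38 ± 0.52 for Arg1, 0.58 ± 0.59 for Cxcl1, 0.88 ± 0.32 for Osm (0.632) and -0.30 ± 0.43 for Cxcl15. With all libraries DESeq2 called 12 genes (10 higher, 2 lower), limma 0 (76 unadjusted) and a fit to only these arms 0.

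Among gene lists in the same comparison, the 16 tested liver markers had a median log2 fold of 5.94 with 16 of 16 positive. Of these markers 12 were called over all genes and 14 when adjusted over the list alone, yet the list itself did not pass (fry adjusted p = 0.214). Complement genes had a median of 1.35 with 17 of 20 positive (fry adjusted p = 0.174), with Cfb at 2.26 ± 0.54, C4b at 3.01 ± 0.72 and C6 at 3.81 ± 0.95. Of the complement list, 8 members were called over all genes and 12 when adjusted over the list alone. Without TP-0903 replicate 3 and Vehicle replicate 3 the liver markers had a median of 0.53 with 11 of 16 positive and complement genes 0.48 with 15 of 20 positive, and Cfb had a log2 fold of -0.08 ± 0.33, C4b 0.72 ± 0.50 and C6 0.48 ± 0.50. The neutrophil list had a median of 0.44 with 17 of 19 positive (fry adjusted p = 0.174), led by Cxcl1, Osm, Cxcl2 at 1.43 ± 0.48 and Cxcl3 at 1.18 ± 0.45. Of its members 2 were called over all genes and 3 when adjusted over the list alone.

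**Figure D2:**
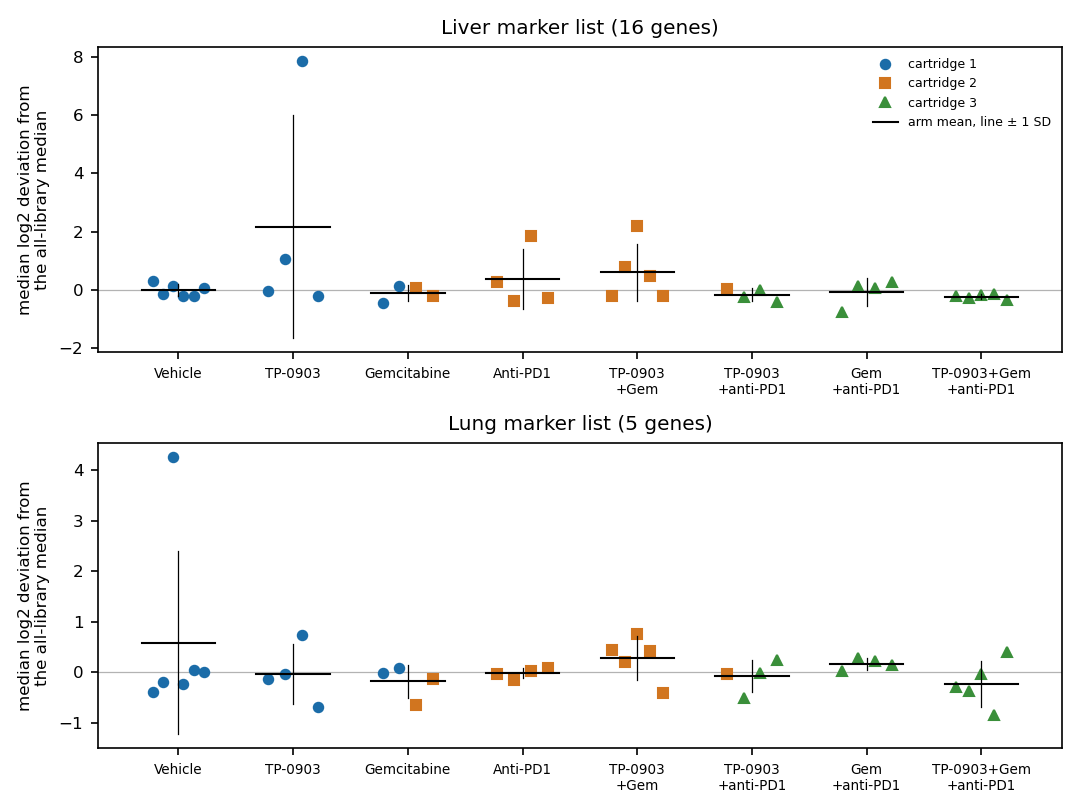
Median log2 deviation of 16 liver markers and of 5 lung markers from the all-library median, 1 point per tumour, by arm. TP-0903 replicate 3 lay at 7.87 for liver and Vehicle replicate 3 at 4.26 for lung, above all other tumours, which reached 2.19 and 0.75.

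Gemcitabine alone against vehicle asked what the cytotoxic drug does by itself. The neutrophil granule enzyme Mpo had a log2 fold of 4.59 ± 1.11 (295 ± 468 against 12.2 ± 7.14 scaled counts, n = 4 and 6, 4 of 4 above the vehicle mean), and the neutrophil elastase gene Elane 3.66 ± 0.97 (at least 3.40-fold). Lower values were those of Cxcl15 at -6.90 ± 1.61, Lamp3 at -4.82 ± 1.22 and the integrin gene Itgae at -0.91 ± 0.26. The 2 lung genes rested on Vehicle replicate 3, without which Cxcl15 had -0.17 ± 0.40 and Lamp3 0.05 ± 0.31. Mpo and Elane stood at 992 and 520 scaled counts in Gemcitabine replicate 1, against 13.6 to 148 and 10.6 to 114 in the rest of the arm. Lymph node or spleen markers lay 1.55 log2 units above the all-library median in that tumour, so such tissue was not excluded there. Log2 folds of Mpo and Elane were 2.35 and 1.87 at the lowest under the alternatives. None of these 5 passed, with edgeR adjusted p-values from 0.0876 for Mpo and Cxcl15 to 0.228 for Itgae. edgeR called 0 genes (62 unadjusted), limma 0 (23 unadjusted) and DESeq2 2, both higher. Without Vehicle replicate 1, 2, 4 or 5 edgeR called 2 lower genes and without Vehicle replicate 6 it called 1. With the cartridge as a block it called 2 higher genes, and between the lanes that shared cartridge 1 it called 4. No list passed (smallest fry adjusted p = 0.892).

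Anti-PD1 alone against vehicle addressed checkpoint blockade without another drug. The lung genes Cxcl15 and Lamp3 had log2 folds of -7.13 ± 1.63 and -5.08 ± 1.23 (Lamp3 at least 1.76-fold lower, n = 4 and 6), the endothelial anticoagulant gene Thbd -2.77 ± 0.90, the angiopoietin receptor gene Tek -2.55 ± 0.86 and Tdo2 3.79 ± 1.25. Tdo2 rested on Anti-PD1 replicate 3, with 926 scaled counts against at most 27.0 in the other 3, and was -0.09 ± 1.21 without it. None passed (smallest edgeR adjusted p = 0.0880), and edgeR called 0 genes (39 unadjusted), DESeq2 0 (40 unadjusted) and limma 0 (6 unadjusted). Without Vehicle replicate 1, 2, 4, 5 or 6 the count was 2, both lower, and with the title digit as a block it was 2. Without Vehicle replicate 3 and TP-0903 replicate 3 it was 0 (36 unadjusted), with Cxcl15 at -0.41 ± 0.40 and Thbd at 0.49 ± 0.36. The endothelial list had a median of -1.20 (fry adjusted p = 0.673), with 2 members lower when adjusted over the list alone and 0 called over all genes. Besides Thbd and Tek it was led by the integrin ligand gene Icam2 at -2.11 ± 0.80 and by Vwf, which encodes von Willebrand factor, at -1.95 ± 0.70. Its medians against vehicle lay between -1.23 and -0.70 in the 7 treated arms and, without Vehicle replicate 3, between 0.13 and 0.47. Without that library and TP-0903 replicate 3, Icam2 had 0.55 ± 0.36 and Vwf 0.26 ± 0.29 in this comparison.

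TP-0903+Gemcitabine against vehicle addressed Axl inhibition with chemotherapy. The inflammatory cytokine gene Tnf rose by a log2 fold of 1.22 ± 0.27, from 18.6 ± 3.56 to 44.1 ± 17.5 scaled counts (n = 6 and 5, adjusted p = 0.0147). In scaled counts, 5 of 5 treated tumours lay above every vehicle tumour. Tnf was near background in vehicle tumours, whose lane thresholds lay between 17.4 and 26.3 raw counts. The separation of the arms was not tested on raw counts. Over the alternatives the log2 fold of Tnf ran from 0.43 to 2.20. The pancreatic phospholipase gene Pla2g1b rose by 5.54 ± 1.16 (761 ± 1305 against 16.4 ± 10.5, adjusted p = 0.0144, 5 of 5 above the vehicle mean). The other tested marker of normal pancreas, Dmbt1, had a log2 fold of 0.13 ± 0.82 (adjusted p = 0.948). Dmbt1 stood at 10328 to 53939 scaled counts in vehicle tumours other than replicate 3. Its flat fold therefore does not check for normal pancreas tissue in tumours with high Pla2g1b. Cxcl15 was called lower at a log2 fold of -7.00 ± 1.47 (at least 2.01-fold lower), which rested on Vehicle replicate 3 and was -0.29 ± 0.38 without it, with Lamp3 then at 0.48 ± 0.29. With all libraries Lamp3 at -4.38 ± 1.08 (0.0510) and the eosinophil granule gene Prg2 at 2.69 ± 0.70 (0.0653, at least 1.91-fold) did not pass. edgeR called these 3 genes and 102 had an unadjusted p under 0.05. Without TP-0903+Gemcitabine replicate 3 the count was 0, with Tnf at 0.97 ± 0.26 and Pla2g1b at 3.50 ± 1.00, and it was 0 without Vehicle replicate 3 and 5 without Vehicle replicate 1, 4 or 6. DESeq2 called 20 genes (6 higher, 14 lower), limma 0 (68 unadjusted), edgeR with the cartridge as a block 0 (72 unadjusted) and with the title digit as a block 13. The direction of calls depended on the scaling: positive controls alone gave 2 higher and 138 lower genes while the median over all genes went from 0.07 to -0.59, and TMM gave 1 higher and 1 lower. The ratio of housekeeping to positive-control counts ran from 0.141 to 0.341 in this arm and from 0.279 to 0.457 in vehicle. Scaling to positive controls alone carries that difference into every fold.

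No inflammatory list passed in the TP-0903+Gemcitabine arm. With positive controls only the medians were -0.10 for neutrophils, -0.15 for NF-kB genes, -0.18 for mast cells and eosinophils and -0.03 for B cells. That scaling moved all genes alike, to a median of -0.59, so each of these lists still lay above the median of all genes. The values that follow are scaled to housekeeping genes. The neutrophil list had a median of 0.70 with 18 of 19 positive (fry adjusted p = 0.0575), led by the chemokine genes Cxcl2 at 1.64 ± 0.47, Cxcl3 at 1.44 ± 0.42 and Cxcl1 at 2.45 ± 0.73 and by Mpo at 2.82 ± 1.04. None of its members was called over all genes and 4 were when adjusted over the list alone. NF-kB and inflammatory cytokine genes had a median of 0.55 with 19 of 23 positive (fry adjusted p = 0.0575), with Tnf, Cxcl2, Cxcl1 and the monocyte chemokine Ccl2 at 1.55 ± 0.57 in front. Of that list 1 member was called over all genes and 3 when adjusted over the list alone. The mast cell and eosinophil list had a median of 0.52 (fry adjusted p = 0.0701), led by Prg2, the eosinophil receptor Ccr3 at 1.61 ± 0.61, Ccl24 at 1.21 ± 0.64 and the tryptase Tpsab1 at 0.52 ± 0.30. B cell genes had a median of 0.64 with 16 of 16 positive (fry adjusted p = 0.256), led by the complement receptor Cr2 at 1.36 ± 0.42, Tnfrsf13c at 0.64 ± 0.30, Blk at 1.04 ± 0.51 and Ms4a1 at 1.26 ± 0.69. Of the B cell list and of the mast cell and eosinophil list 1 member each was called when adjusted over the list alone and 0 over all genes.

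TP-0903+anti-PD1 against vehicle addressed Axl inhibition with checkpoint blockade. Neutrophil granule and alarmin genes led: S100a8 had a log2 fold of 3.36 ± 0.85 (6791 ± 9231 against 664 ± 497 scaled counts, n = 4 and 6, 4 of 4 above every vehicle tumour), the antimicrobial peptide gene Camp 3.64 ± 0.94, Mpo 4.24 ± 1.10 and Elane 3.48 ± 0.97. These genes and the lower Cxcl15 (-6.54 ± 1.60) and Lamp3 (-5.10 ± 1.25, at least 1.58-fold) did not pass singly, with edgeR adjusted p-values of 0.0763, or 0.0889 for Elane. TP-0903+anti-PD1 replicate 3 stood at 20616 scaled counts for S100a8 against 1452 to 2598 in the rest of the arm, and highest for Camp and Mpo. At the lowest under the alternatives S100a8 had 1.72, Camp 2.10 and Mpo 2.69. The 2 lung genes had 0.14 ± 0.41 (Cxcl15) and -0.20 ± 0.33 (Lamp3) without Vehicle replicate 3. As a group the neutrophil list rose, with a median of 0.81, a mean of 1.32 and 18 of 19 members positive (fry adjusted p = 0.0208). Of its members 0 were called over all genes and 8 when adjusted over the list alone. This was the only list called by fry among the 23 tested in each of 16 comparisons, and camera gave it an adjusted p = 0.0195 with an estimated correlation. The call was lost without Vehicle replicate 1 (adjusted p = 0.0723, median 0.78), without TP-0903+anti-PD1 replicate 3 (0.202, median 0.58), with positive controls only (0.294, median 0.56), in a fit to only these arms (0.209), with the cartridge as a block (0.512, median 1.09) and with that block and Vehicle replicate 3 and TP-0903 replicate 3 left out (0.393, median 1.13). Over single genes edgeR called 0 (73 unadjusted), limma 0 (44 unadjusted) and DESeq2 8, 7 of them higher. Without TP-0903+anti-PD1 replicate 2 edgeR called 3 genes, and without Vehicle replicate 1, 2, 4, 5 or 6 it called 2 lower genes.

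Gemcitabine+anti-PD1 against vehicle addressed chemotherapy with checkpoint blockade. Pla2g1b rose by a log2 fold of 5.46 ± 1.18 (717 ± 1283 against 16.4 ± 10.5 scaled counts, n = 4 and 6, adjusted p = 0.0420), with 2 of 4 tumours above the vehicle mean. Dmbt1 had 0.70 ± 0.87, which does not check for normal pancreas tissue, since Dmbt1 was abundant in most tumours. Ada, which encodes the purine enzyme adenosine deaminase, had a log2 fold of 1.01 ± 0.25 (adjusted p = 0.0657, 4 of 4 above every vehicle tumour) and did not pass. Nor did Cxcl15 at -6.61 ± 1.59 (0.0657), Lamp3 at -4.56 ± 1.20 or the transferrin receptor gene Tfrc at -1.27 ± 0.34 (0.114). Cxcl15 had 0.11 ± 0.39 and Lamp3 0.31 ± 0.30 without Vehicle replicate 3. The single call, among 72 genes with an unadjusted p under 0.05, rested on Gemcitabine+anti-PD1 replicate 4, without which Pla2g1b had 2.24 ± 1.00 (adjusted p = 0.482). The count was also 0 without Vehicle replicate 2, 3, 4, 5 or 6, 3 without Vehicle replicate 1, and 2 without Gemcitabine+anti-PD1 replicate 1 or 3. DESeq2 called 2 higher and 2 lower genes, limma 0 (33 unadjusted) and edgeR with the cartridge as a block 0 (32 unadjusted), and positive controls alone gave 1 higher and 1 lower. Macrophage genes had a median of 0.64 with 21 of 24 positive (fry adjusted p = 0.278), led by the fungal receptor Clec7a at 1.18 ± 0.33, the oxidase Cybb at 0.80 ± 0.29, C1qa at 0.77 ± 0.32 and Cd86 at 0.75 ± 0.32. The neutrophil list had a median of 0.53 with 18 of 19 positive (0.156) and the NF-kB list a median of 0.42 (0.158). Of the macrophage list 1 member and of the neutrophil list 0 members were called when adjusted over the list alone.

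The triple combination against vehicle addressed all 3 agents together. Mpo rose by a log2 fold of 4.81 ± 1.10 (343 ± 445 against 12.2 ± 7.14 scaled counts, n = 5 and 6, adjusted p = 0.0217) and Elane by 3.76 ± 0.95 (0.0484, at least 4.46-fold), each with 5 of 5 tumours above every vehicle tumour. Mpo was highest in replicates 5 and 3 of the triple arm, at 1054 and 512 scaled counts. Lymph node or spleen markers lay 1.36 and 0.36 log2 units above the all-library median there, so such tissue was not excluded. In the rest of the arm these markers lay below that median, with Mpo at 32.9 to 74.5. Tfrc, an iron uptake receptor of dividing cells, fell by a log2 fold of -1.43 ± 0.32, from 579 ± 194 to 215 ± 32.9 (0.0217), with 5 of 5 tumours below every vehicle tumour. Cxcl15 at -7.18 ± 1.49 (at least 2.75-fold lower), Lamp3 at -4.98 ± 1.13 and C7 at -4.14 ± 1.04 (at least 1.37-fold lower) also fell. edgeR called these 6 genes, 2 higher and 4 lower, and 88 had an unadjusted p under 0.05. Without Vehicle replicate 3 and TP-0903 replicate 3 it called 0 (60 unadjusted), with Mpo at 5.17 ± 1.23 (0.0757), Tfrc at -1.47 ± 0.32 (0.0521) and Elane at 3.87 ± 1.05 (0.126) little moved and Cxcl15, Lamp3 and C7 at -0.46 ± 0.40, -0.09 ± 0.30 and -0.44 ± 0.48. The count was 0 without Vehicle replicate 3 or without replicate 3 of the triple arm, 3 without replicate 5 of that arm, 10 without Vehicle replicate 1 and 11 without Vehicle replicate 4. DESeq2 called 6 higher and 6 lower genes, limma 1 and edgeR with the cartridge or the title digit as a block 0, while TMM gave 3 higher and 4 lower. The neutrophil list had a median of 0.31 with 15 of 19 positive (fry adjusted p = 0.692), led by Mpo, Elane, Camp at 2.75 ± 0.89 and Cxcl3 at 1.21 ± 0.43. Of its members 2 were called over all genes and 4 when adjusted over the list alone.

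**Figure D3:**
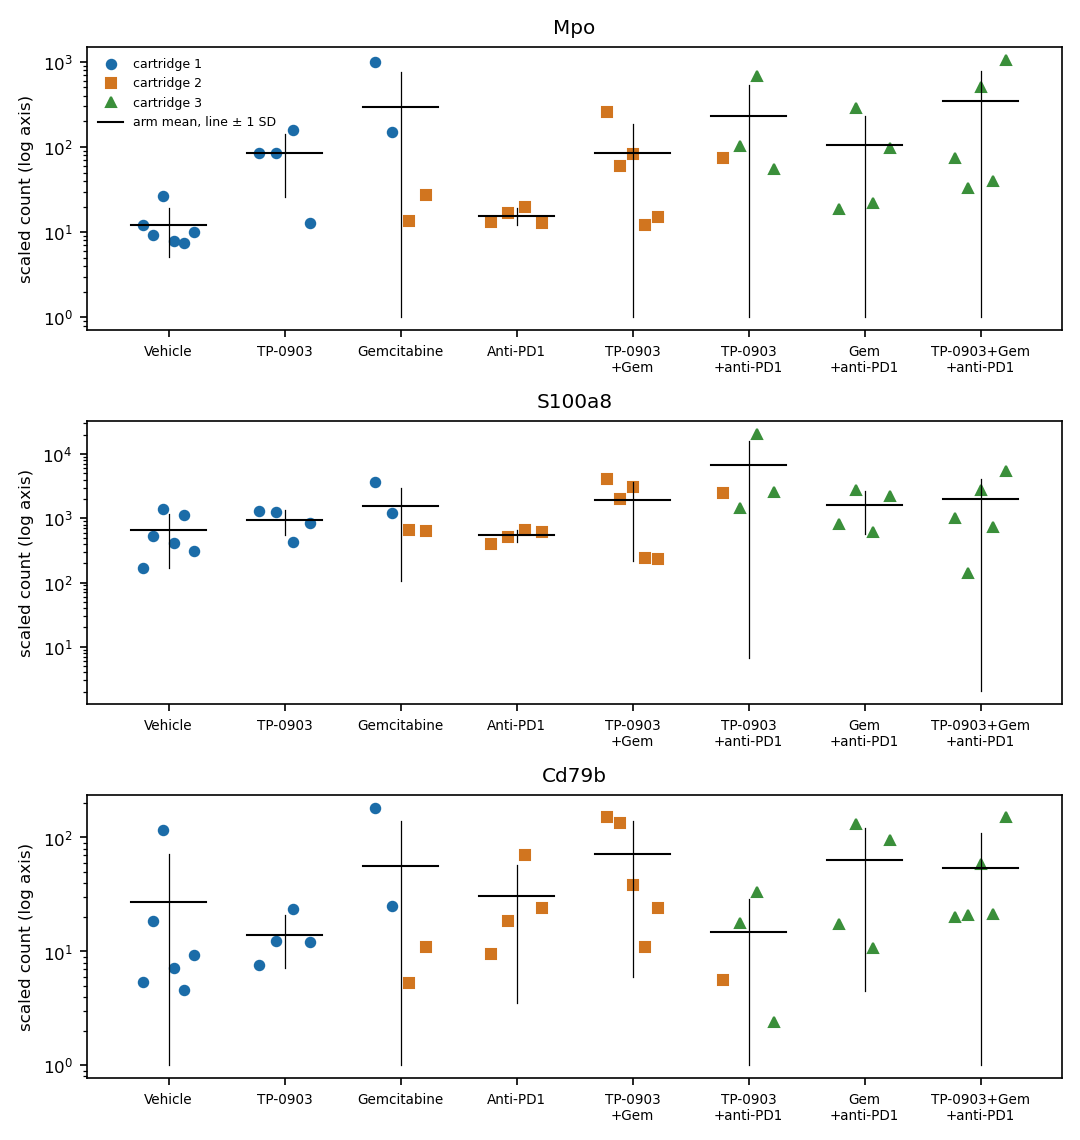
Housekeeping-scaled counts of Mpo, S100a8 and Cd79b in each tumour by arm, on a log axis. Mpo exceeded every vehicle tumour in 5 of 5 triple-therapy tumours.

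Adding TP-0903 to another regimen was tested in 3 comparisons. Over Gemcitabine, the thymic regulator gene Aire had a log2 fold of 1.20 ± 0.28 and Pla2g1b 5.77 ± 1.41 (n = 5 and 4, both adjusted p = 0.0949), ahead of the osteoclast cytokine Tnfsf11 at 1.23 ± 0.37, the granulocyte regulator Gfi1 at 1.29 ± 0.41 and Slamf6 at 1.13 ± 0.36. Suppressive myeloid genes had a median of 0.76 with 16 of 17 positive (fry adjusted p = 0.182), led by the nitric oxide synthase Nos2 at 0.90 ± 0.33, the arginase Arg2 at 1.06 ± 0.45, the scavenger receptor Cd163 at 1.55 ± 0.68 and Mrc1 at 0.87 ± 0.47, with 0 members called when adjusted over the list alone. Over Anti-PD1, S100a8 had 3.63 ± 1.01, the mast cell chymase Cma1 2.09 ± 0.62, Tfrc -1.17 ± 0.36, Camp 3.36 ± 1.08 and Mpo 3.87 ± 1.27 (n = 4 and 4, smallest adjusted p = 0.542), and the neutrophil list had a median of 0.57 with 19 of 19 positive (fry adjusted p = 0.315; 4 members called when adjusted over the list alone). TP-0903+anti-PD1 replicate 3 stood highest of its arm for S100a8, Camp and Mpo. At the lowest under the alternatives they had 1.99, 1.82 and 2.25. Over Gemcitabine+anti-PD1, the inflammasome gene Mefv had -1.50 ± 0.37 (adjusted p = 0.181, n = 5 and 4), Pla2g1b -4.08 ± 1.20, Slamf7 -1.22 ± 0.45, the interferon regulator Irf7 -1.20 ± 0.47 and Ada -0.65 ± 0.26. Single tumours weighed on Pla2g1b, at 2637 scaled counts in Gemcitabine+anti-PD1 replicate 4 (7.57 to 216 in the rest of the arm). In the first comparison it stood at 3068 in TP-0903+Gemcitabine replicate 3 (30.9 to 533). None of these genes passed, and edgeR called 0 genes in each comparison, with 53, 29 and 17 at an unadjusted p under 0.05. DESeq2 called 1, 1 and 0, and limma 0, 0 and 1. Without TP-0903+Gemcitabine replicate 1 or 5 the first comparison gave 2 genes or 1, and without replicate 5 of the triple arm the last gave 1. The median over all genes in the first comparison was 0.20, against 0.04 with TMM and -0.47 with positive controls only.

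The average effect of TP-0903 over 4 backgrounds (18 against 18 tumours) was led by Cxcl1 at 1.56 ± 0.41, above the comparison mean in 15 of 18 tumours, the chemokine Ccl26 at -0.66 ± 0.19, Tfrc at -0.57 ± 0.17, below that mean in 17 of 18, H2-Q10 at 1.94 ± 0.59 and the neutrophil protease Ctsg at 1.40 ± 0.43. None passed (smallest edgeR adjusted p = 0.317), and edgeR called 0 genes (78 unadjusted), DESeq2 0 (74 unadjusted) and limma 0 (51 unadjusted). Without Vehicle replicate 3 and TP-0903 replicate 3, Cxcl1 had 0.73 ± 0.29 (adjusted p = 0.370), H2-Q10 0.27 ± 0.38 and Ctsg 1.35 ± 0.45. The neutrophil list had a median of 0.33 with 18 of 19 positive (fry adjusted p = 0.192), led by Cxcl1, Mpo at 1.64 ± 0.56, Camp at 1.33 ± 0.48 and S100a8. Of its members 6 were called when adjusted over the list alone and 0 over all genes.

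The average effect of gemcitabine (18 against 18 tumours) raised Pla2g1b by a log2 fold of 3.15 ± 0.63 (adjusted p = 0.0138), with 13 of 18 tumours above the comparison mean. Cr2, a complement receptor of B cells, at 1.03 ± 0.24, the complement gene Hc at -2.80 ± 0.69, Clec7a at 0.70 ± 0.17 and C9 at -1.97 ± 0.51 had edgeR adjusted p-values of 0.0613 and did not pass. C9 stood at 7237 scaled counts in TP-0903 replicate 3, given no gemcitabine, against 14.4 to 50.5 in the rest of that arm. Over the alternatives Hc ran from -2.98 to -0.34 and C9 from -2.07 to -0.41. B cell genes had a median of 0.35 with 15 of 16 positive (fry adjusted p = 0.635), led by Cr2, the antigen receptor gene Cd79b at 1.59 ± 0.52, the CD20 gene Ms4a1 at 1.18 ± 0.39 and Tnfrsf13c at 0.46 ± 0.17. Of these 3 were called when adjusted over the list alone. edgeR called 1 gene, with 98 at an unadjusted p under 0.05. The count was 17 without Vehicle replicate 3 and TP-0903 replicate 3 and 0 with the cartridge as a block (45 unadjusted). Leaving out 1 library gave 13, 12 or 11 genes without TP-0903 replicate 1, 2 or 4, 10 without TP-0903+Gemcitabine replicate 3, 8 or 5 without Anti-PD1 replicate 4 or 2, and 4 without Vehicle replicate 3. It gave 2 without Gemcitabine replicate 3, TP-0903+Gemcitabine replicate 5 or replicate 2 of the triple arm, and 0 without Gemcitabine replicate 4 or Gemcitabine+anti-PD1 replicate 4. DESeq2 called 9 higher and 17 lower genes, limma 0 (56 unadjusted), TMM gave 3 higher, and positive controls alone gave 2 higher and 17 lower.

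The average effect of the antibody (17 against 19 tumours) was led by liver genes, C8g at -1.94 ± 0.50, Saa1 at -1.98 ± 0.61, C8a at -2.14 ± 0.68 and H2-Q10 at -1.85 ± 0.59, and by the dendritic cell activation gene Cd83 at -0.62 ± 0.19, below the comparison mean in 15 of 17 tumours. None passed (smallest edgeR adjusted p = 0.334), and edgeR called 0 genes (39 unadjusted), limma 0 (17 unadjusted) and DESeq2 1. Without TP-0903 replicate 1 or 4 edgeR called 1. Without Vehicle replicate 3 and TP-0903 replicate 3, C8g had -0.44 ± 0.20, Saa1 -0.87 ± 0.48, C8a -0.59 ± 0.46 and H2-Q10 -0.17 ± 0.38, none of them called. T cell core genes had a median of -0.12, cytotoxic lymphocyte genes -0.20 and MHC class I genes -0.29 with 0 of 13 positive, each at a fry adjusted p of 0.841. For MHC class I, Vehicle replicate 3 and TP-0903 replicate 3, given no antibody, lay 2.41 and 1.54 log2 units above the all-library median. They lay at 0.97 and 0.75 for T cell core genes and at 0.84 and 1.04 for cytotoxic lymphocyte genes. The negative list medians can therefore not be read apart from these 2 tumours.

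Interactions asked whether an agent acted differently in the presence of another. Between TP-0903 and the antibody, 10 liver genes were called, all negative: Hamp at -7.24 ± 1.61, Tdo2 at -7.03 ± 1.41, Saa1 at -6.13 ± 1.23, H2-Q10 at -5.94 ± 1.21, Ambp at -5.91 ± 1.32, F12 at -5.75 ± 1.22, Mbl2 at -5.28 ± 1.18, C8b at -4.52 ± 0.97, C8g at -4.15 ± 0.99 and C9 at -4.06 ± 1.01 (adjusted p from 0.00655 to 0.0243, 79 genes unadjusted). The liver list had a median of -4.11 with 0 of 16 positive (fry adjusted p = 0.266). The count was 0 without TP-0903 replicate 3, 22 without TP-0903 replicate 1, 16 without TP-0903 replicate 4 or TP-0903+Gemcitabine replicate 5, and 0 without TP-0903 replicate 3 and Vehicle replicate 3 together (73 unadjusted), where Hamp had -4.53 ± 1.17 and Tdo2 -3.96 ± 1.07 (both 0.124). DESeq2 called 1 gene, limma 0 (60 unadjusted) and edgeR with the cartridge as a block 0. Between TP-0903 and gemcitabine edgeR called 0 genes (35 unadjusted, DESeq2 1, limma 0), with Saa1 at -4.58 ± 1.20, C9 at -3.32 ± 1.00, the adhesion gene Ceacam1 at -1.37 ± 0.42, Mpo at -3.37 ± 1.10 and the NK receptor Klra2 at 0.73 ± 0.24 not past the threshold (smallest adjusted p = 0.425). Without TP-0903+Gemcitabine replicate 3 it called 1, and without Vehicle replicate 3 and TP-0903 replicate 3 Saa1 had -2.30 ± 0.97 and C9 -0.33 ± 0.46. Between gemcitabine and the antibody it also called 0 (25 unadjusted, DESeq2 0, limma 0), led by S100b at -0.94 ± 0.27 (smallest adjusted p = 0.878).

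**Figure D4:**
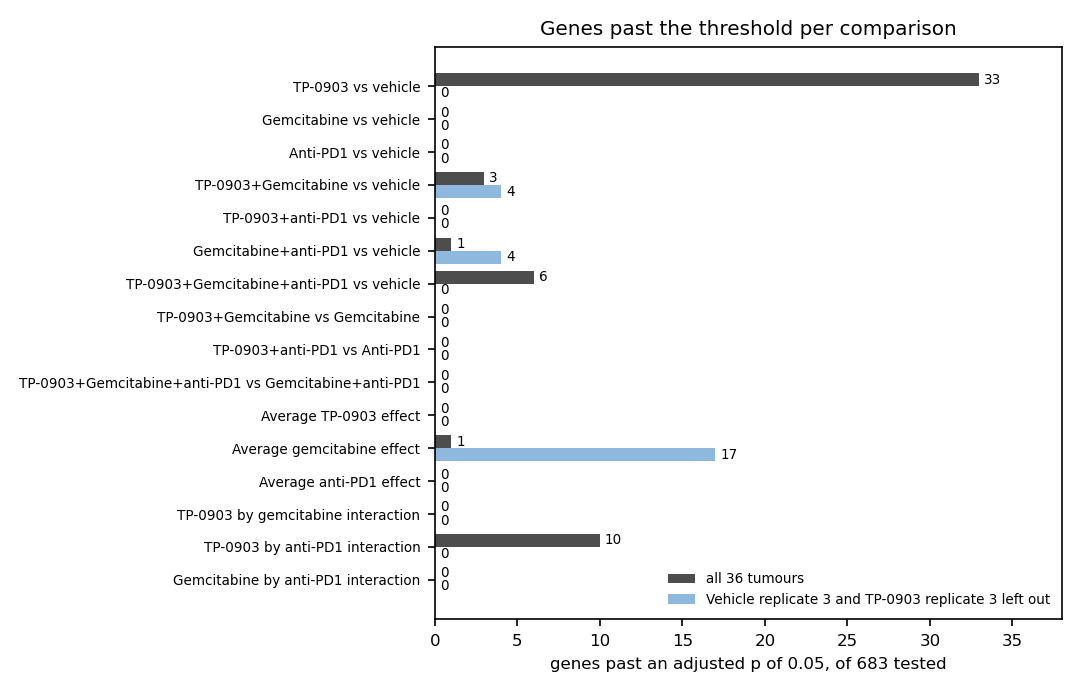
Number of genes past the threshold in each comparison with all 36 libraries and with 2 libraries left out, from edgeR. TP-0903 against vehicle went from 33 to 0 and the average gemcitabine effect from 1 to 17.

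Of the remaining lists, the smallest fry adjusted p over the 16 comparisons was 0.322 for T cell core and for cytotoxic lymphocytes and NK cells (both TP-0903 over Gemcitabine), 0.266 for regulatory and helper T cell factors and for dendritic cells (TP-0903 by antibody interaction), and 0.259 for immune checkpoints and for lymph node or spleen markers (TP-0903+Gemcitabine). It was 0.655 for MHC class I, TAM receptor pathway, epithelial and cell cycle genes (average gemcitabine effect), 0.673 for MHC class II, type I interferon and stroma (Anti-PD1), 0.669 for interferon gamma induced genes (TP-0903 over Gemcitabine) and 0.616 for endothelial genes (TP-0903+Gemcitabine). It was 0.259 for macrophages in TP-0903+Gemcitabine against vehicle.

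The single-agent comparisons shared their vehicle tumours, so their log2 folds correlate without any effect. Across 683 genes, which are not independent replicates, Pearson's r was 0.377 between TP-0903 and Gemcitabine (simulated without effects 0.380; with separate vehicle tumours for each -0.02), 0.613 between TP-0903 and Anti-PD1 (0.387; 0.202) and 0.666 between Gemcitabine and Anti-PD1 (0.397; -0.10). The covariances were 0.325, 0.493 and 0.311 against simulated values of 0.0808, 0.0816 and 0.0841. Shared calls could only number 0, since Gemcitabine and Anti-PD1 had 0 calls each, so the overlap of calls was not tested. Without Vehicle replicate 3 and TP-0903 replicate 3 the covariances were 0.148, 0.103 and 0.0813 against simulated values of 0.0653, 0.0645 and 0.0639.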

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

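Every test that weighs an explanation in this part, each count over other splits of the samples and each fit without 2 or 3 libraries was chosen after the result had been seen. Groups of 4 to 6 tumours were searched for a highest or lowest tumour standing far from its own arm, for median correlation with other libraries, for the neutrophil and liver lists and for named genes. Of 89 such groups, 28 had such a tumour, where chance alone marks about 1 in 20 groups, or 5%. TP-0903 replicate 3 accounted for 14 and Vehicle replicate 3 for 7. That share does not hold for named genes, many of which were called because of these tumours and vary together, so the 28 were not tested against chance.

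Liver transcripts stood out in TP-0903 replicate 3. Scaled counts there were 74795 for Ambp (59.3 to 282 in the other 3 TP-0903 tumours), 40065 for H2-Q10 (29.8 to 199), 32044 for Hamp (22.1 to 150), 9961 for Tdo2 (11.5 to 84.5), 7591 for Saa1 (17.4 to 228), 7237 for C9, 6487 for Mbl2, 4791 for C8g, 3649 for C8a and 3136 for F12. Lamp3 at 23.6 and C7 at 33.4 were also the highest of the arm. The liver list's median lay 7.87 log2 units above the all-library median against -0.23 to 1.07 in the other 3, and the tumour's median correlation with other libraries was 0.542 against 0.940 to 0.955. Tumour and epithelial genes were lower there: the epithelial list stood at -3.63, Cdh1 at 485 scaled counts (1761 to 2526), Epcam at 43.2 scaled counts (2142 to 2293), Msln at 57.0 (3590 to 4830) and Dmbt1 at 25.5 (14159 to 30580).

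For the rise of liver genes after TP-0903, 3 explanations were weighed. The 30 called higher genes had a median log2 fold of 3.77 with all tumours and 0.52 without replicate 3 (quartiles 0.17 and 0.87). These values argue against a rise of the called size in every TP-0903 tumour. The genes were called with replicate 3 in the fit, so a lower median without it was bound to follow. A smaller rise in the other TP-0903 tumours is not argued against. Scaling to housekeeping genes is argued against as the cause, since 31 of the 33 calls were also made with TMM. Liver tissue in the dissected sample is a candidate explanation that remains open: the liver list stood at 7.87 in that tumour, and the most abundant markers were Ambp, H2-Q10 and Hamp. Of the 16 liver markers 2 belong to other lists as well. An exchange of this sample for a specimen of liver stays open as well, since the same values, with Epcam at 43.2 there, go with it. A metastasis or tumour growing into liver is a biological alternative that was not tested.

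Lung and vessel transcripts stood out in Vehicle replicate 3. Cxcl15 stood at 12336 scaled counts there (9.95 to 40.1 in the other 5 vehicle tumours), Lamp3 at 2254 (7.39 to 20.4) and C7 at 1005 (7.22 to 26.8). Hamp at 155 (8.54 to 17.6), Mpo at 26.3 (7.39 to 12.2) and C8g at 20.02 (11.8 to 14.2) were the highest of the arm too. Its median correlation with other libraries was 0.703 against 0.942 to 0.952 in the other vehicle tumours. Epcam stood at 397 there (836 to 2646), Msln at 265 (3096 to 8225) and Dmbt1 at 69.6 (10328 to 53939).

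For the lower lung and vessel genes of treated arms, treatment as the cause is argued against for the vessel genes, because the endothelial list's median over the 7 treated arms went from -1.08 to 0.31 without Vehicle replicate 3 (0.13 to 0.47 over arms). Lung tissue in that vehicle sample is a candidate explanation: the median of 5 lung markers lay at 4.26 there against -0.39 to 0.05 in the other vehicle tumours, with Cxcl15, Lamp3 and Foxj1 (277 scaled counts) among them. Chil3, a lung marker at 2286 there, was also high elsewhere, at 3569 in TP-0903+anti-PD1 replicate 3, and Marco stood at 71.7 there against 448 in TP-0903 replicate 3, so neither marks that library. An exchange of that sample for a specimen holding lung stays open as well. A lung metastasis in the mouse sampled is a biological alternative that was not tested.

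Neutrophil genes in TP-0903+anti-PD1 were weighed as the last pattern. In list medians 4 of 4 treated tumours lay above each vehicle tumour, which a response in every tumour would give. The list was picked because it was called on these values, so this is no separate test of a response. The lowest treated tumour lay at 0.16 and the highest vehicle tumour at 0.11. Gemcitabine+anti-PD1 replicates 1, 2 and 4 also lay above each vehicle tumour, at 0.20, 0.18 and 0.25, and replicate 3 did not (0.099). With the cartridge as a block the list's median was 1.09 in place of 0.81, but the adjusted p went to 0.512, so a difference between cartridges cannot be told apart from treatment for an arm that shared no cartridge with vehicle. Spleen or lymph node tissue cannot be told apart either: that list's median without Vehicle replicate 3 was 0.57 (standard error 0.178, fry adjusted p = 0.912), below the neutrophil list's 1.05 in the same fit but not under a bound that would exclude it, and 7 of its 12 markers belong to other lists. Among 100 splits of these 10 tumours, 4 gave at least 1 called list, the highest of the others 5. This comparison was picked from 16 because it held a called list, so chance was not excluded.

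Further tumours far from their arm were found for other values. Pla2g1b stood at 3068 scaled counts in TP-0903+Gemcitabine replicate 3 (30.9 to 533 in the rest of the arm) and at 2637 in Gemcitabine+anti-PD1 replicate 4 (7.57 to 216). Tfrc stood at 961 in Vehicle replicate 6 (424 to 569) and Ambp at 518 in Vehicle replicate 1 (24.2 to 147). The median correlation of Gemcitabine replicate 1 was 0.915 (0.950 to 0.956 in its arm). The neutrophil list stood at -0.0556 in TP-0903 replicate 4 (0.0720 to 0.0892) and at 0.422 in Gemcitabine replicate 2 (-0.299 to -0.183). No explanation was tested for these tumours.

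Liver genes were called in the tested interaction of TP-0903 with the antibody, which does not establish an effect of TP-0903 on them. Log2 values of the interaction were -7.24 for Hamp, -7.03 for Tdo2, -6.13 for Saa1, -5.94 for H2-Q10, -5.91 for Ambp, -5.75 for F12, -5.28 for Mbl2, -4.52 for C8b, -4.15 for C8g and -4.06 for C9. The edgeR calls depended on TP-0903 replicate 3, without which 0 genes were called, but the folds did not rest on it alone. Over all alternatives Hamp ran from -8.00 to -2.13 and Tdo2 from -7.23 to -1.80. Hamp also stood at 1216 scaled counts in Anti-PD1 replicate 3 and at 1066 in TP-0903+Gemcitabine replicate 3. Of 100 splits, 6 gave at least 10 genes and the highest of the others 79, so chance cannot be excluded.

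Other splits of the same tumours were counted for each comparison. Against vehicle, 64 of 100 splits gave at least as many genes as TP-0903 (33, highest other 225), 58 as TP-0903+Gemcitabine (3, highest other 178), 54 as Gemcitabine+anti-PD1 (1, highest other 86) and 45 as the triple combination (6, highest other 80). Where no gene was called, genes at an unadjusted p under 0.05 were counted instead, and 74 of 100 splits gave as many for Gemcitabine (62, highest other 204), 99 for Anti-PD1 (39, highest other 202) and 70 for TP-0903+anti-PD1 (73, highest other 239). For TP-0903 added to Gemcitabine, 17 of 100 did (53, highest other 103), for TP-0903 added to Anti-PD1, 15 of 35 (29, highest other 105), and for TP-0903 added to Gemcitabine+anti-PD1, 40 of 100 (17, highest other 79). For the averages, 30 of 100 did for TP-0903 (78, highest other 171), 81 for the antibody (39, highest other 145) and 16 for gemcitabine by called genes (1, highest other 28). For the interactions without calls, 79 did between TP-0903 and gemcitabine (35, highest other 174) and 97 between gemcitabine and the antibody (25, highest other 184). Chance could not be excluded for any count in this paragraph. Splits that called several times the real count, as in the comparisons with vehicle, point to a structure of the samples. Its origin was not tested. TP-0903 added to Anti-PD1, a comparison without TP-0903 replicate 3 or Vehicle replicate 3, also gave splits several times the real count. That comparison held Anti-PD1 replicate 3, whose liver list stood at 1.85, so it was not free of liver transcripts.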

How the results depend on the processing

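Fits without 2 libraries (Vehicle replicate 3 and TP-0903 replicate 3) or 3 (also TP-0903+Gemcitabine replicate 3), alone or with another scaling, test or block, comparisons within 1 cartridge and list tests with a cartridge block were chosen after the results had been seen, and the other alternatives were planned. Counts are genes past the threshold from edgeR unless a tool is named, and except where stated the cause was not tested.

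The targets Axl and Pdcd1 stayed short of the threshold in all 153 tests of them under alternatives, with average log2 folds without single libraries of -0.0282 to 0.0882 for Axl with TP-0903 and -0.33 to -0.19 for Pdcd1 with the antibody. Their signs changed in 22 of these tests, with values near 0. The average for Axl was -0.00575 with TMM, -0.16 with positive controls only, -0.0301 with DESeq2, -0.0413 with limma and -0.0527 with limma after background subtraction, and that for Pdcd1 0.0237 with the last. Axl in TP-0903 against vehicle ran from -0.34 to 0.13 without single libraries and was 0.0792 without 2, without 3, and without 2 with the cartridge block, and 0.11 without 2 with limma. Pdcd1 in Anti-PD1 was 0.0149 with the cartridge block.

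Over the genes named, 2681 tests under alternatives gave the same direction and side of the threshold, 413 lost a call, 126 gained one and 78 reversed, most of them short of the threshold either way. Over lists, by the direction of the test, 564 gave the same, 54 gained a call, 6 lost one and 13 reversed. Comparisons whose count of calls no alternative moved by over 1.5 times were the average TP-0903 effect and the interaction of gemcitabine with the antibody, at 0.

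Without single libraries the counts ran from 0 to 47 for TP-0903 against vehicle, 0 to 2 for Gemcitabine, 0 to 2 for Anti-PD1, 0 to 5 for TP-0903+Gemcitabine, 0 to 3 for TP-0903+anti-PD1, 0 to 3 for Gemcitabine+anti-PD1 and 0 to 11 for the triple combination. They ran from 0 to 2 for TP-0903 added to Gemcitabine, 0 to 0 for TP-0903 added to Anti-PD1 and 0 to 1 for TP-0903 added to Gemcitabine+anti-PD1. For averages they ran from 0 to 0 (TP-0903), 0 to 13 (gemcitabine) and 0 to 1 (antibody), and for interactions from 0 to 1 (TP-0903 by gemcitabine), 0 to 22 (TP-0903 by antibody) and 0 to 0 (gemcitabine by antibody). Called lists ran from 0 without Vehicle replicate 1 to 6 without Vehicle replicate 3, against 1 with all libraries. The count for TP-0903 went from 33 to 0 without TP-0903 replicate 3, which held the liver transcripts.

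DESeq2 called 12 genes for TP-0903 against vehicle, 2 for Gemcitabine, 20 for TP-0903+Gemcitabine, 8 for TP-0903+anti-PD1, 4 for Gemcitabine+anti-PD1 and 12 for the triple combination. It called 1 for TP-0903 added to Gemcitabine, 1 for TP-0903 added to Anti-PD1, 26 for the average gemcitabine effect, 1 for the average antibody effect, 1 for the TP-0903 by gemcitabine interaction and 1 for the TP-0903 by antibody interaction.

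Limma on log2 scaled counts called 0 for TP-0903, 0 for TP-0903+Gemcitabine, 0 for Gemcitabine+anti-PD1, 1 for the triple combination, 1 for TP-0903 added to Gemcitabine+anti-PD1, 0 for the average gemcitabine effect and 0 for the TP-0903 by antibody interaction, and 4 lists. After background subtraction limma gave 0 for TP-0903, 0 for TP-0903+Gemcitabine, 0 for Gemcitabine+anti-PD1, 2 for the triple combination, 0 for the average gemcitabine effect and 0 for the TP-0903 by antibody interaction, and 3 lists.

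The stricter filter left 19 calls for TP-0903, 2 for the triple combination and 3 for the TP-0903 by antibody interaction, since fewer genes were tested. Fits to only the groups compared gave 0 for TP-0903, 0 for TP-0903+Gemcitabine, 0 for Gemcitabine+anti-PD1 and 1 for the triple combination, with 2 lists called in the pairwise comparisons in place of 1.

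Positive controls alone gave 140 for TP-0903+Gemcitabine, 2 for Gemcitabine+anti-PD1, 10 for the triple combination, 19 for the average gemcitabine effect and 4 lists. With that scaling the median log2 fold of all genes was -0.59 for TP-0903+Gemcitabine, -0.24 for TP-0903+anti-PD1, -0.23 for the triple combination, -0.47 for TP-0903 added to Gemcitabine, -0.20 for the average TP-0903 effect, -0.18 for the average gemcitabine effect, -0.22 for the TP-0903 by gemcitabine interaction and 0.14 and 0.36 for the interactions of the antibody with TP-0903 and gemcitabine. Lists reversed mostly with it, within this shift. In TP-0903+Gemcitabine medians were then -0.51 for the cytotoxic list, which was called, -0.46 for immune checkpoints, -0.40 for dendritic cells, -0.18 for mast cells and eosinophils and -0.15 for NF-kB genes. For TP-0903 added to Gemcitabine they were -0.36 for immune checkpoints, -0.0544 for mast cells and eosinophils and 0.0737 for suppressive myeloid genes, and for type I interferon in Gemcitabine+anti-PD1 -0.24. Limma after background subtraction reversed the cytotoxic list (-0.28) and dendritic cells (0.10) in TP-0903+Gemcitabine. Without single libraries dendritic cells ran from -0.18 to 0.54 there and type I interferon in Gemcitabine+anti-PD1 from -0.25 to 0.48. TMM gave 3 for the average gemcitabine effect, 4 lists and a correlation of 0.591 between Gemcitabine and Anti-PD1. Camera with the preset correlation of 0.01 called 86 lists, 49 higher and 37 lower.

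The cartridge as a block gave 2 for Gemcitabine, 0 for TP-0903+Gemcitabine, 0 for Gemcitabine+anti-PD1, 0 for the triple combination, 0 for the average gemcitabine effect, 0 for the TP-0903 by antibody interaction and 0 lists. Arms that share no cartridge with vehicle were then compared only through other arms, which widens their errors. Within 1 cartridge TP-0903 against vehicle gave 0 and Gemcitabine 4. The title digit as a block gave 2 for Anti-PD1, 13 for TP-0903+Gemcitabine, 0 for Gemcitabine+anti-PD1, 0 for the triple combination, 2 for the average gemcitabine effect and 5 lists.

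Leaving out 2 libraries gave 0 for TP-0903, 4 for Gemcitabine+anti-PD1, 0 for the triple combination, 17 for the average gemcitabine effect, 0 for the TP-0903 by antibody interaction and 11 lists. Correlations between comparisons were then 0.608 for TP-0903 and Gemcitabine, 0.483 for TP-0903 and Anti-PD1 and 0.344 for Gemcitabine and Anti-PD1. Leaving out 3 gave 0 for TP-0903, 0 for TP-0903+Gemcitabine, 3 for Gemcitabine+anti-PD1, 0 for the triple combination, 4 for the average gemcitabine effect, 0 for the TP-0903 by antibody interaction and 5 lists. With 2 libraries left out and TMM these were 0 for TP-0903, 9 for TP-0903+Gemcitabine, 0 for Gemcitabine+anti-PD1, 0 for the triple combination, 16 for the average gemcitabine effect, 0 for that interaction and 4 lists.

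With 2 left out and limma they were 0 for TP-0903, 0 for TP-0903+Gemcitabine, 3 for Gemcitabine+anti-PD1, 1 for the triple combination, 1 for TP-0903 added to Gemcitabine+anti-PD1, 0 for the average gemcitabine effect, 0 for the TP-0903 by antibody interaction and 6 lists. With 2 left out DESeq2 gave 0 for TP-0903, 2 for Gemcitabine, 1 for Anti-PD1, 43 for TP-0903+Gemcitabine, 14 for TP-0903+anti-PD1, 13 for Gemcitabine+anti-PD1, 2 for TP-0903 added to Gemcitabine, 8 for TP-0903 added to Anti-PD1, 40 for the average gemcitabine effect and 2 for the TP-0903 by antibody interaction. With 2 left out and the cartridge as a block edgeR gave 0 for TP-0903, 3 for Gemcitabine, 16 for TP-0903+Gemcitabine, 1 for the triple combination, 0 for the average gemcitabine effect, 0 for the TP-0903 by antibody interaction and 11 lists, another set than the 11 without the block.

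Genes called with all libraries reversed only where Vehicle replicate 3 or TP-0903 replicate 3 was left out. For Ambp in TP-0903 against vehicle, log2 folds without single libraries ran from -0.14 to 7.80, the lowest without TP-0903 replicate 3. It was -0.37 without 2 libraries, without 3, and without 2 with the cartridge block, -0.53 with TMM, -0.19 with limma and -0.59 with DESeq2. Lamp3 in the same comparison ran from -4.91 to 0.20, the highest without Vehicle replicate 3, and was 0.0602 with limma and 2 libraries left out. In the triple combination with 2 libraries left out and the cartridge block, Lamp3 was 0.46 and C7 0.0771.

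Among genes short of the threshold, Lamp3 in Gemcitabine, TP-0903+Gemcitabine and Gemcitabine+anti-PD1 was 0.0459, 0.48 and 0.31 with 2 libraries left out, 0.0454, 0.42 and 0.31 with 3, 0.0197, 0.25 and 0.10 with 2 and TMM, 0.0813, 0.49 and 0.35 with 2 and limma, and 0.22, 0.81 and 0.87 with 2 and the cartridge block. With 2 left out and DESeq2 it was 0.23 and 0.0990 in the last 2 of these, and with the cartridge block 0.13 in Anti-PD1 and 0.30 in TP-0903+anti-PD1. Without single libraries it ran from -5.08 to 0.0461, -4.64 to 0.48 and -4.82 to 0.31 in the first 3. Cxcl15 in TP-0903+anti-PD1 and Gemcitabine+anti-PD1 ran from -7.19 to 0.14 and -6.87 to 0.11 without single libraries. It was 0.14 and 0.11 with 2 left out, 0.14 and 0.11 with 3, 0.17 and 0.24 with 2 and limma, and in the former 0.0335 with 2 and TMM and 0.0318 with 2 and DESeq2.

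Thbd and Tek in Anti-PD1 ran from -3.22 to 0.49 and -2.92 to 0.50 without single libraries. They were 0.49 and 0.50 with 2 left out and with 3, 0.30 and 0.32 with 2 and TMM, 0.38 and 0.41 with 2 and limma, 0.33 and 0.34 with 2 and DESeq2, and 0.72 and 0.77 with 2 and the cartridge block. Tdo2 in Anti-PD1 ran from -0.0864 without Anti-PD1 replicate 3 to 4.19. Pla2g1b for TP-0903 added to Gemcitabine+anti-PD1 was 0.14 with limma after background subtraction. Ada in Gemcitabine+anti-PD1 was -0.00907 with 2 left out and the cartridge block.

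C8g and C9 in the interaction of gemcitabine with the antibody ran from -0.18 to 2.96 and -0.13 to 3.19 without single libraries. They were -0.23 and -0.16 with 2 left out, -0.16 and -0.0756 with 2 and TMM, -0.0722 and -0.23 with 2 and limma, -0.17 and -0.0903 with 2 and DESeq2, and -0.87 and -0.76 with 2 and the cartridge block, and C8g was -0.0247 with 3. For the average antibody effect C8a, H2-Q10 and Saa1 were 0.70, 0.57 and 0.45 with 2 left out and the cartridge block, and H2-Q10 0.16 with 3. H2-Q10 in the average TP-0903 effect was -0.0694 with 3.

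No paired analysis was possible because replicate numbers follow the order of the samples and tie no tumours together. Limma on the authors' normalized values, with a pseudocount of 1 and of 20, was not run, since the deposited table holds raw counts. Depth limits genes near background, such as Pdcd1, and 67 genes were not tested.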

Other observations

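The fits without Vehicle replicate 3 and TP-0903 replicate 3, and the genes named from them, were chosen after the values had been seen, and so was the count over other splits. Both libraries came from arms without gemcitabine, and no gemcitabine tumour was left out. Vehicle replicate 3 and TP-0903 replicate 3 had type I interferon scores of 1.76 and 1.53 and B cell scores of 1.11 and 0.51. Leaving them out therefore lowers the values that gemcitabine tumours are compared with. With those libraries left out, genes of B cells were among those called higher in the average gemcitabine effect. The antigen receptor gene Cd79b rose by a log2 fold of 2.05 ± 0.49 (61.3 against 16.2 scaled counts, 14 of 18 gemcitabine tumours above the comparison mean), the CD20 gene Ms4a1 by 1.40 ± 0.39, Cr2 by 1.09 ± 0.25, Cd180 by 0.98 ± 0.28 and Cd22 by 0.76 ± 0.20. Interferon-stimulated genes called higher were Ifit3 by 0.85 ± 0.23, Isg15 by 0.74 ± 0.19, Irf7 by 0.64 ± 0.16, Oas2 by 0.55 ± 0.15 and Ifit1 by 0.47 ± 0.12. Mpo rose by 2.20 ± 0.60, the platelet chemokine Ppbp by 1.59 ± 0.44, the lymphocyte receptor Slamf1 by 0.99 ± 0.27, Clec7a by 0.72 ± 0.18 and Pla2g1b by 3.22 ± 0.68. Tfrc fell by a log2 fold of -0.62 ± 0.17 and Stat3, a cytokine signalling factor, by -0.28 ± 0.08, below the mean in 18 of 18. Tumours above the comparison mean numbered 14 of 18 for Cr2, 13 for Pla2g1b, 11 for Ms4a1, 9 for Ppbp and 8 for Mpo. edgeR called these 17 genes, 15 higher and 2 lower, at an adjusted p of 0.0380 for Pla2g1b, 0.04997 for Cd180 and 0.0481 for the other 15. edgeR called 4 when TP-0903+Gemcitabine replicate 3 was left out as well, and with TMM 11 higher and 5 lower. DESeq2 called 20 higher and 20 lower, limma 0 and edgeR with the cartridge as a block 0 (84 unadjusted), with Cd79b then at 2.69 ± 0.90 (adjusted p = 0.202). Of 100 splits of the tumours 1 gave as many genes, the real one, and the highest of the others gave 6, but the fit itself was picked after the values had been seen, so this share does not exclude chance. Cartridge and treatment cannot be separated fully here, since the block widened the errors and ended every call. As lists, B cell genes had a median of 0.48 with 15 of 16 positive and type I interferon genes 0.22 with 20 of 22 positive, both at a fry adjusted p of 0.134. With all libraries the type I interferon median was 0.00 (0.911). Lymph node or spleen markers, 7 of 12 of which belong to other lists, had a median of 0.60 with 12 of 12 positive (fry adjusted p = 0.314). In the 5 gemcitabine-treated tumours with the highest B cell scores, Gemcitabine replicate 1, TP-0903+Gemcitabine replicates 1 and 2, Gemcitabine+anti-PD1 replicate 2 and replicate 5 of the triple arm, B cell scores ran from 0.83 to 1.46 and those of lymph node or spleen markers from 1.36 to 1.73. Tissue of lymph node or spleen in these samples was therefore not excluded.

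Without the same libraries, 11 lists were called by fry, all higher, against 1 higher and 3 lower with TMM. Leaving out TP-0903+Gemcitabine replicate 3 as well gave 4 higher and 1 lower, so the calls and their direction depended on scaling and on single tumours. In TP-0903+Gemcitabine against vehicle these were lymph node or spleen markers (median 1.48, 12 of 12 positive, adjusted p = 0.0399), B cells (0.96, 16 of 16, 0.0321), neutrophils (0.92, 19 of 19, 0.0298), mast cells and eosinophils (0.59, 0.0388), NF-kB genes (0.54, 0.0298), dendritic cells (0.54, 0.0499), cytotoxic lymphocytes (0.47, 0.0499) and immune checkpoints (0.37, 0.0499). In TP-0903+anti-PD1 the neutrophil list was called (1.05, 0.0160). In Gemcitabine+anti-PD1 the neutrophil list (0.69, 0.0464) and type I interferon genes (0.48, 19 of 22, 0.0464) were called, the latter with Ifit1 at 1.12 ± 0.23, Irf7 at 1.32 ± 0.30 and Isg15 at 1.51 ± 0.36 called singly. With the cartridge as a block in the same fit 11 lists were called as well, but another set, all in TP-0903+Gemcitabine against vehicle or against Gemcitabine. The neutrophil call in TP-0903+anti-PD1 (adjusted p = 0.393) and both list calls in Gemcitabine+anti-PD1 were lost, and so were the single calls of Ifit1 at 1.62 ± 0.59 (0.322), Irf7 at 1.48 ± 0.77 (0.506) and Isg15 at 2.22 ± 0.92 (0.389). These folds did not shrink, and the calls ended because the errors widened in arms that shared no cartridge with vehicle. None of the 11 without the block held with an estimated correlation (camera adjusted p from 0.151 to 0.884). In TP-0903+Gemcitabine 4 genes were called higher, Pla2g1b at 5.82 ± 1.29, Ppbp at 3.54 ± 0.85, Cxcl1 at 2.33 ± 0.52 and Tnf at 1.16 ± 0.28. With the cartridge as a block Ppbp stayed called at 6.58 ± 1.51 (adjusted p = 0.0264). Cxcl1 at 2.97 ± 1.00 (0.100), Tnf at 1.42 ± 0.51 (0.108) and Pla2g1b at 4.10 ± 2.68 (0.366) did not, with wider errors and, for Pla2g1b, a smaller fold. The count was 0 when replicate 3 of the arm was left out as well, 0 with limma (139 unadjusted), 3 higher and 6 lower with TMM, and 15 higher and 28 lower with DESeq2.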
